A study of Drosophila melanogaster with 15 samples.

How the data were processed

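Gene expression was measured in whole Drosophila melanogaster larvae with Affymetrix arrays of the first Drosophila genome design, in 15 arrays that form 5 groups of 3. The deposited values are intensities, given as 1 signal per probe set on a linear scale. Per the labels, the authors made these signal intensities with Microarray Suite (MAS) version 5.0 at its default settings, and global scaling was their normalization. The submitters' processing notes name MAS5 as well. The trimmed mean signal, leaving out 2% of the probe sets at each end, was between 800.2 and 800.25 on every array, which is what scaling to 1 target leaves. No detection calls were used here, so a low signal was not separated into detected and not detected. Sequencing depth does not apply to arrays.

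The table held 14010 probe sets, of which 44 were Affymetrix controls and were left out of the tests. Gene names came from the platform's annotation, with symbols looked up by Entrez gene identifier in the RefSeq table of the Drosophila Release 6 assembly. There were 12444 probe sets with exactly 1 symbol, 327 with several and 1196 non-control probe sets that this annotation does not name. Of the probe sets with 1 symbol, 12394 were found in the RefSeq table, none of their symbols changed, and 50 kept the annotation's symbol. A probe set with several symbols was never used to name a gene. An unnamed probe set is given by its identifier, at most 2 rises and 2 falls per comparison. No build is given for the array design in the sources used here, so no coordinates are printed.

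Each sample was RNA from a pool of 20 larvae, taken 2 h after injection of about 0.1 microliter of fluid, with about 25 micrograms of total RNA used for labelling, per the labels. Groups were taken from the source names and treatment protocols. The labels of the mutant arrays conflict: the titles of all 9 hold the letters ctr, while their treatment text names E. coli. The titles of the wild type PBS arrays hold ctr too, and those of the wild type E. coli arrays hold inj instead. The treatment text was followed here, which does not settle the conflict. The wild type genotype of the other 6 arrays follows from the series design, because their own labels name no mutation. No PBS-injected mutants were analysed here, so a difference between a mutant and wild type can be a difference between stocks that exists without bacteria. Nothing in the labels says that the pools of a group came from separate cultures, so the p-values measure the spread between these pools, part of which may be technical. Titles give the same number to wild type PBS replicates 2 and 3, to wild type E. coli replicates 2 and 3 and to dorsal mutant replicates 1 and 2, and the labels do not say whether such arrays come from 1 culture or extract. These pairs correlated at 0.940, 0.929 and 0.932, the highest of their groups, where the other pairs reached 0.939, 0.929 and 0.884.

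Signals were analysed as log2(signal + 80), the pseudocount of 80 being 0.1 of the median trimmed mean. Differences on this scale understate the change of genes with low signals. A probe set was tested when its signal was at least 160 on at least 3 arrays, which left 11427 probe sets and removed 2539. One linear model with a mean per group was fitted to all 15 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes with a variance trend), with 10 residual degrees of freedom. Its moderated test was two-sided, p-values were adjusted with the Benjamini-Hochberg method over the probe sets tested, and a probe set was called at an adjusted p under 0.05. All adjusted p-values in the text come from this fit unless a gene list is named. The comparisons were bacteria against PBS in wild type, each mutant against wild type with bacteria, and the 3 pairs of mutants. Each mutant was also set against wild type with PBS, for a measure of distance from the uninfected state.

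There were 25 gene lists fixed before the data were examined, tested with camera at the preset inter-gene correlation of 0.01 and again with the correlation estimated for each list, with adjustment over the lists of 1 comparison. Each gene entered with its probe set of highest mean signal, which gave 9190 genes. The cytochrome P450 list was built from a symbol pattern, and 2 cyclophilins that matched the pattern (Cyp1 and Cyp40) were taken out after the data were seen. Of the 14 antimicrobial peptide genes listed, 6 had a tested probe set with a single symbol. Whether the others enter the tests through unnamed probe sets or those with several symbols was not examined. Members of multigene families can share probe sequence, so values of single cecropin, glutathione S-transferase and P450 genes are uncertain.

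The genes named in the text were also chosen by a rule fixed before the data were examined. Rel, Dif and dl came first, in every comparison. In each of the 4 main comparisons the rule took the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups, every tested antimicrobial peptide gene, and up to 4 called members of each other list described, or up to 2 uncalled ones as values. In each pair of mutants it took the 3 largest rises and the 3 largest falls.

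The model was tested on simulated data with the spread of the real probe sets and 200 changed probe sets among 11427. In the simulated comparison of wild type E. coli with wild type PBS, 79.5% of the changes of 2 on the log2 scale and 15.8% of the changes of 1 were recovered, and 4.87% of the calls were false. A shift added to every gene of the antimicrobial peptide list was found in 20 of 20 simulated sets. The simulated noise was independent between genes and between arrays, so these rates leave out any correlation in the real data.

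Within groups the arrays correlated between 0.881 and 0.940 over probe sets, and no pair of columns was identical. The ratio of 3' to 5' actin control signals, a measure of RNA integrity, ran from 1.65 to 6.27 over the arrays. That of GAPDH ran from 2.25 to 6.03 and that of eIF-4a from 3.96 to 14.8, both highest on Relish mutant replicate 1. The hybridization control CreX read 8029.9 on wild type PBS replicate 1 and between 41319 and 100510 on the others. Alternatives covered quantile and cyclic loess normalization, other pseudocounts and filters, the variance model, array weights, fits of only the groups compared, the replicate number as a block, averaging of arrays whose titles share a number, and each array left out in turn. Another filter also changes which listed genes enter a gene list. A covariate for the salivary glue level and a blocked fit of the 6 wild type arrays were added after seeing the data.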

Results

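The series measured transcripts of Drosophila melanogaster larvae of the third instar after septic injury, to see how mutations of the 3 NF-kappaB factors of the fly alter the response to a Gram-negative bacterium. Wild type larvae were injected with phosphate buffered saline (PBS) or with Escherichia coli. Larvae carrying the Relish allele E20, the Dif allele 1 or the dorsal allele 1 were injected with E. coli according to their treatment text, although the titles of these 9 arrays hold the letters ctr. Titles of the wild type PBS arrays hold these letters as well, and those of the wild type E. coli arrays do not. Relish is the factor of the Imd pathway, and Dif and dorsal are factors of the Toll pathway. RNA was taken 2 h after injection from pools of 20 larvae, with 3 arrays in each of the 5 groups. The scaled signals of 11427 probe sets were compared, with medians between 245.5 and 340.5 signal units over the arrays. All log2 differences refer to log2(signal + 80), and errors of signals are standard deviations over 3 arrays.

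The transcripts of the mutated genes were examined first. Rel read 18.9, 11.4 and 27.4 signal units on the Relish mutant arrays, all below the pseudocount. It read 807.0, 663.6 and 721.8 in wild type with PBS and 4980.7, 3095.2 and 3328.6 in wild type with E. coli. On the Dif mutant arrays Rel read 1091.5, 1191.2 and 1272.7, and on the dorsal mutant arrays 1186.9, 373.5 and 1306.5. The Dif transcript read 210.0, 213.8 and 204.3 in the Dif mutant, against 246.0, 255.0 and 338.3 in wild type with E. coli and 115.3, 167.2 and 234.1 with PBS. On the dorsal mutant arrays Dif read 210.1, 155.8 and 98.5, and on the Relish mutant arrays 34.6, 28.1 and 258.3. The dl transcript read 195.8, 180.1 and 414.0 in the dorsal mutant, against 722.9, 329.6 and 311.9 in wild type with E. coli and 305.9, 215.3 and 237.8 with PBS. It read 193.4, 373.6 and 257.9 in the Dif mutant and 35.9, 320.7 and 162.3 in the Relish mutant. The log2 difference of Dif in its own mutant was -0.31 (SE 0.41, adjusted p = 0.761) and that of dl was -0.62 (SE 0.44, adjusted p = 0.547). These probe sets therefore bear on the labels of the Relish arrays and leave those of the Dif and dorsal arrays unchecked.

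Bacteria raised antimicrobial peptide genes in wild type larvae. DptB, a diptericin gene, stood at 14708 ± 6127 signal units with E. coli and 1248.7 ± 457.3 with PBS (n = 3 each), a log2 difference of 3.47 (SE 0.45, adjusted p = 0.00155). The cecropin gene CecB rose by 3.76 (SE 0.50) from 165.8 ± 98.2 to 3164.1 ± 1140.9 units. Rel itself rose by 2.23 (SE 0.34, adjusted p = 0.00459). The tyrosine hydroxylase gene ple rose by 3.22 (SE 0.62) and the beta-alanyl-dopamine synthase gene e (ebony) by 2.21 (SE 0.39). The other named rises were CG14567 at 3.81 (SE 0.53), CG11529 at 2.36 (SE 0.46), CG12826 at 1.67 (SE 0.21) and CG42562 at 1.56 (SE 0.27). The single fall was Npc2d, of the Niemann-Pick type C2 family, from 1956.4 ± 178.8 to 633.9 ± 30.1 units, or -1.51 (SE 0.29). In all, 17 probe sets were called higher and 1 lower, and 8 of these 18 had no gene name, among them 143443_at at 5.20 and 143097_f_at at 4.65. At an unadjusted p under 0.05 there were 540, and 12.0% of the probe sets had no overlap between the groups, where chance gives 10%.

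The antimicrobial peptide list rose in wild type with bacteria, with a median log2 difference of 2.32 over 6 genes (camera adjusted p = 2.06e-17, and adjusted p = 0.00251 with an estimated correlation). Of its members 2 passed over all probe sets and 6 when adjusted over the list alone. The uncalled members read 2.72 (SE 0.58) for the metchnikowin gene Mtk, 1.91 (SE 0.50) for the defensin gene Def, 1.47 (SE 0.41) for the attacin gene AttD and 0.94 (SE 0.42) for the drosomycin gene Drs. Secreted peptides known as Toll targets had a median of 0.91 over 8 genes (adjusted p = 1.04e-04, but adjusted p = 0.157 with an estimated correlation). None of them was called and 2 passed when adjusted over the list alone, and BomS5 read 1.80 and BomBc2 1.09. Microbial recognition proteins had a median of 0.35 over 9 genes (adjusted p = 2.34e-04, but adjusted p = 0.0924 with an estimated correlation), with no member called, 1 when adjusted over the list alone, and PGRP-SB1, a peptidoglycan amidase, at 3.32. The wound and JNK list had a median of 0.33 over 18 genes (adjusted p = 2.34e-04, but adjusted p = 0.152 with an estimated correlation), with ple as its called member and 3 when adjusted over the list alone. The Toll pathway list at 0.33 over 15 genes and the muscle list at 0.30 over 15 genes passed with adjusted p = 0.0261 and 7.08e-04, but with an estimated correlation the adjusted p was 0.229 and 0.152. No member of either was called, and 1 and 0 passed when adjusted over the list alone, with SPE at 1.05 and Act79B at 0.56. The Toll pathway list was not called without wild type PBS replicate 2 (0.18, adjusted p = 0.0867), without wild type E. coli replicate 1 (0.28, adjusted p = 0.0882) or under the stricter filter (0.18, adjusted p = 0.121). With their calls kept, the secreted peptides lay at 0.57 without wild type E. coli replicate 1, the recognition proteins at 0.77 without wild type PBS replicate 2, and the wound and JNK list at 0.19 without wild type PBS replicate 2, 0.18 without wild type E. coli replicate 3 and 0.50 under the stricter filter. The other 19 lists did not pass, with medians from -1.31 for the salivary glue proteins to 0.17 for the heat shock proteins. The count of calls was 10 without wild type E. coli replicate 1 and 11 without replicate 3, and it was 58 with array weights, 31 with only the groups compared in the fit and 87 in these 6 arrays with the replicate number as a block, chosen after seeing the data. DptB, CecB, CG14567 and CG12826 kept their calls without each of the 6 arrays, whereas Rel lost its call without wild type E. coli replicate 1 (2.02, adjusted p = 0.0623), and ple, CG11529, e, CG42562 and Npc2d lost theirs without several arrays each, at adjusted p between 0.0521 and 0.346.

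**Figure D1:**
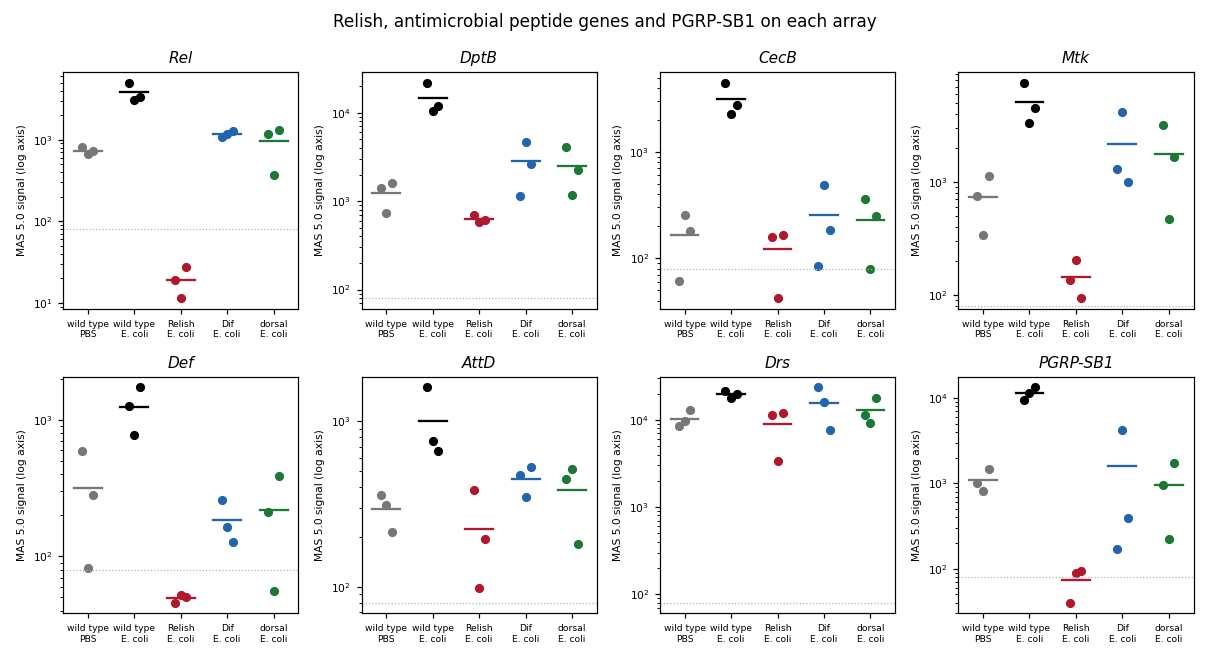
Each panel plots the signal of 1 gene on a log axis for the 15 arrays, with the 5 groups along the horizontal axis, points for arrays, bars for group means and a dotted line at the pseudocount of 80. The 3 wild type E. coli arrays were highest for DptB, between 10452 and 21731, and Rel was between 11.4 and 27.4 on the Relish mutant arrays.

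In the Relish mutant 5 of the 6 antimicrobial peptide genes tested were called lower than in wild type larvae with bacteria. DptB stood at 629.4 ± 57.4 signal units against 14708 ± 6127, a log2 difference of -4.31 (SE 0.45, adjusted p = 3.67e-05). Mtk (-4.49, SE 0.58), CecB (-4.02, SE 0.50), Def (-3.30, SE 0.50) and AttD (-1.85, SE 0.41) fell as well, while Drs read -1.33 (SE 0.42, adjusted p = 0.140) and was not called. The list median was -3.66 (camera adjusted p = 2.82e-15, and adjusted p = 0.00426 with an estimated correlation), and 5 of 6 members were called lower, 6 when adjusted over the list alone. PGRP-SB1 fell by 6.23 (SE 0.74), from 11485 ± 1917.1 to 74.3 ± 29.8 units, a mean below the pseudocount. PGRP-SC2, another peptidoglycan amidase gene, rose by 2.18 (SE 0.46), and the recognition list as a whole did not pass (median -0.42, adjusted p = 0.210). Rel fell by 5.26 (SE 0.34). The dopa decarboxylase gene Ddc fell by 3.72 (SE 0.71), and ple read -3.62 (SE 0.62).

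Toll-responsive secreted peptides were lower in the Relish mutant too, with a median of -2.21 over 8 genes (adjusted p = 5.75e-05, but adjusted p = 0.140 with an estimated correlation). The members called were BomS5 at -3.39, BomBc2 at -2.84 and BomS2 at -2.38, and 5 were lower and 1 higher when adjusted over the list alone. The Toll pathway list had a median of -0.58 (adjusted p = 0.00282, but adjusted p = 0.140 with an estimated correlation), where the receptor gene Tl (-1.47) and the protease gene SPE (-1.15) were called and 6 passed when adjusted over the list alone. The wound and JNK list had a median of -0.38 (adjusted p = 0.00422, but adjusted p = 0.229 with an estimated correlation), with Ddc, ple and kay called, and 4 lower and 1 higher when adjusted over the list alone. Another probe set of kay read -0.05. The JAK-STAT list had 3 tested members and a median of -0.82 (adjusted p = 0.00282, but adjusted p = 0.108 with an estimated correlation). Stat92E was called at -0.97, with another probe set at -0.06, and 2 passed when adjusted over the list alone. Hemocyte markers had a median of 0.28 (adjusted p = 0.0270, but adjusted p = 0.140 with an estimated correlation). The members called were the crystal cell prophenoloxidase genes PPO1, from 1290.8 ± 361.2 to 7651.1 ± 1091.3 units or 2.52 (SE 0.24), and PPO2 at 1.94, of which another probe set read 0.25, and 3 passed when adjusted over the list alone. Male germline genes had a median of 0.63 (adjusted p = 0.0270, but adjusted p = 0.601 with an estimated correlation) with no member called, Mst84Db at 1.63 and ocn at 1.07. Cytoplasmic ribosomal protein genes had a median of -0.18 (adjusted p = 0.00282, but adjusted p = 0.601 with an estimated correlation) with no member called, RpL37A at -1.08 and RpS19b at -0.79. When adjusted over the list alone neither list had a member that passed. Apart from the estimated correlation, the calls of 4 of these lists were lost under other settings. The Toll pathway list lost it under the stricter filter (-0.23, adjusted p = 0.141), and the ribosomal list without wild type E. coli replicate 2 (-0.12, adjusted p = 0.0692). The hemocyte list lost it without Relish mutant replicate 1 (0.23, adjusted p = 0.105) and without wild type E. coli replicate 1 (0.12, adjusted p = 0.0999) or 3 (0.27, adjusted p = 0.0653). The male germline list lost it without Relish mutant replicate 1 (0.54, adjusted p = 0.112) and without wild type E. coli replicate 2 (0.27, adjusted p = 0.294) or 3 (0.51, adjusted p = 0.138). It also did so under the stricter filter (0.65, adjusted p = 0.0726), with arrays of the same title number averaged (0.39, adjusted p = 0.151) and with the glue level as a covariate, chosen after seeing the data (0.39, adjusted p = 0.0820). With calls kept, the hemocyte list lay at 0.49 without wild type E. coli replicate 2, and the ribosomal list at -0.29 without replicate 1 and at -0.12 with the covariate. The JAK-STAT list lay at -0.53 without Relish mutant replicate 2 and at -0.51 without wild type E. coli replicate 1. With no filter, where listed genes of lower signal joined it, it lay at -0.51. The other 17 lists did not pass, with medians from -0.42 to 0.59.

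Genes outside the lists of defence also differed in the Relish mutant. The glue gene Sgs4 rose by 6.22 (SE 1.10) and the esterase gene alpha-Est2 by 4.89 (SE 0.55), both from wild type means below the pseudocount. The alkaline phosphatase gene Alp7 fell by 5.25 (SE 0.32), from 6130.0 ± 2382.7 to 77.0 ± 32.0 units, and the P450 gene Cyp12d1-d read -3.80 (SE 0.41). The glutathione S-transferase gene GstE1 rose by 2.86 (SE 0.32). CG43798, CG17191, CG14120, Srg2 and CG11892 rose by 2.21 to 3.06, and CG2444 (-4.62) and CG17290 (-3.83) fell. The unnamed probe set 141407_at rose by 7.45 and 147220_s_at fell by 6.14. Altogether 85 probe sets were called higher and 130 lower, and 1533 had an unadjusted p under 0.05. With arrays of the same title number averaged, since these may come from 1 culture or extract, the total was 94. The count was 126 and 141 without Relish mutant replicate 1 and 2, and 137 and 116 without wild type E. coli replicate 2 and 3. Of 41 called genes that the naming rule took, 26 kept their calls without each array, and the 15 that did not were Srg2, CG11892, PGRP-SC2, Ddc, AttD, BomS2, Tl, SPE, kay, Stat92E, fon, Tsf3, Mf, Cyp6a13 and GstE8, at adjusted p between 0.0504 and 0.212.

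On the Dif mutant arrays the mean signals of all 6 antimicrobial peptide genes tested lay between those of the Relish mutant and of wild type with bacteria. CecB stood at 253.1 ± 210.9 signal units against 3164.1 ± 1140.9, a log2 difference of -3.42 (SE 0.50, adjusted p = 7.29e-04). DptB (-2.48, SE 0.45) and Def (-2.31, SE 0.50) fell too. Mtk read -1.41 (SE 0.58), AttD -0.96 (SE 0.41) and Drs -0.45 (SE 0.42), none of them called. The list median was -1.86 (camera adjusted p = 1.65e-06, but adjusted p = 0.0898 with an estimated correlation), with 3 of 6 members called lower and 5 when adjusted over the list alone. PGRP-SB1 fell by 3.84 (SE 0.74), and Rel read -1.59 (SE 0.34, adjusted p = 0.0171). Toll-responsive secreted peptides had a median of -1.75 (adjusted p = 3.27e-05, but adjusted p = 0.208 with an estimated correlation), with BomS5 at -2.87, BomBc2 at -2.84 and BomS2 at -2.04 called and 4 members lower when adjusted over the list alone. The wound and JNK list had a median of -0.31 (adjusted p = 0.00554, but adjusted p = 0.298 with an estimated correlation), where ple (-2.48), kay (-1.21) and Pvr (-1.09) were called and 5 passed when adjusted over the list alone. Another probe set of kay read 0.06. The list stayed called at -0.095 without wild type E. coli replicate 3 and at -0.70 under the stricter filter. The other 21 lists, apart from the heat shock proteins, did not pass, with medians from -0.43 to 1.37.

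Heat shock genes were high on the Dif mutant arrays. The small heat shock gene Hsp26 read 26644, 16333 and 83792 signal units there against 1498.4 ± 405.3 in wild type with E. coli, a log2 difference of 4.43 (SE 0.62, adjusted p = 5.54e-04). Hsp68 rose by 3.49 (SE 0.85), and Hsc70-3, the chaperone of the endoplasmic reticulum, by 1.03. The list median was 1.03 over 9 genes (adjusted p = 2.32e-04, but adjusted p = 0.208 with an estimated correlation), with 3 members called and 5 when adjusted over the list alone. Heat shock genes are known to respond to handling too, and Hsp68 differed between the 3 Dif mutant arrays, at 1413.1, 4878.3 and 30283 units. Without Dif mutant replicate 3 its difference was 2.33 (adjusted p = 0.135).

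Other single genes differed in the Dif mutant too. CG17105 fell by 5.40 (SE 0.51), from 10508 ± 4430.6 to 162.1 ± 66.3 units. CG13135, Jig, Bbd, CG8160 and CG14567 fell, at -4.72 to -3.63, as did the P450 genes Cyp6a14 (-3.95) and Cyp12d1-d (-3.91) and the fatty acid synthase gene FASN1 (-3.09). The alkaline phosphatase gene Alp8 rose by 3.61 (SE 0.31) and the glutathione S-transferase gene GstD5 by 3.39 (SE 0.52). Sgs4 rose by 6.21 (SE 1.10), alpha-Est2 by 4.18, and CG1304, CG17191, CG16727 and CG43798 by 2.89 to 4.31. The unnamed 141407_at and 153583_at rose by 7.52 and 3.89, and 147431_at (-4.42) and 143097_f_at (-4.36) fell. In all, 130 probe sets were called higher and 176 lower, and 1793 had an unadjusted p under 0.05. There were 110 calls with arrays of the same title number averaged, 184 without the variance trend, 164 with only the groups compared in the fit, 183 without Dif mutant replicate 2 and 170, 182 and 153 without wild type E. coli replicates 1, 2 and 3. Of 43 called genes that the naming rule took, 25 kept their calls without each array, and the others were Rel, Hsp68, CG13135, Def, BomS2, SPE, ple, kay, Pvr, Hsc70-3, PPO1, NimC1, Jon66Cii, LysX, LysP, Mf, Cyp28d2 and Cyp6a17, at adjusted p between 0.0506 and 0.152.

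On the dorsal mutant arrays the antimicrobial peptide genes were lower than in wild type with bacteria, to levels near those of the Dif mutant. DptB stood at 2489.3 ± 1448.5 signal units, a log2 difference of -2.61 (SE 0.45, adjusted p = 0.00320). CecB (-3.45, SE 0.50) and Def (-2.27, SE 0.50) fell too, while Mtk read -1.75 (SE 0.58), AttD -1.23 (SE 0.41) and Drs -0.66 (SE 0.42), none of them called. The list median was -2.01 (camera adjusted p = 1.01e-07, but adjusted p = 0.0592 with an estimated correlation), with 3 of 6 members called lower and 5 when adjusted over the list alone. PGRP-SB1 (-3.80, SE 0.74), Rel (-2.03, SE 0.34) and ple (-3.51, SE 0.62) fell. The Toll-responsive secreted peptides did not pass (median -0.14, adjusted p = 0.907), with BomBc3 at 1.72 and BomT3 at 1.52, neither called.

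Genes of the mitochondrial respiratory chain were lower in the dorsal mutant as a group, with a median of -0.80 over 22 genes (camera adjusted p = 1.16e-13, but adjusted p = 0.371 with an estimated correlation). The 4 members called were the ATP synthase genes ATPsynO at -1.18 and blw at -1.10 and the complex I genes ND-51 at -1.15 and ND-75 at -1.02, and 18 passed when adjusted over the list alone. Salivary glue genes had a median of 3.20 over 8 genes (adjusted p = 5.18e-04, but adjusted p = 0.500 with an estimated correlation), with Sgs4 as the called member at 8.35 (SE 1.10) and 2 when adjusted over the list alone. The glue level, a sign of larval stage, differed widely within groups: its mean log2 signal was 14.72, 14.72 and 15.47 on the dorsal mutant arrays and 13.47, 9.21 and 11.55 on the wild type E. coli arrays. The muscle list had a median of -0.37 (adjusted p = 5.18e-04, but adjusted p = 0.261 with an estimated correlation), with Zasp52 at -1.06 and up, the troponin T gene, at -0.91 called, and 3 when adjusted over the list alone. Another probe set of up read 0.55, and other probe sets of Zasp52 read -0.45 and -0.40. Larval cuticle genes had a median of -0.38 (adjusted p = 0.0343, but adjusted p = 0.568 with an estimated correlation), with Ccp84Ag at -2.70 and Edg91 at -1.19 called, and 3 when adjusted over the list alone. The cuticle list was not called without dorsal mutant replicate 3 (-0.18, adjusted p = 0.148) or without wild type E. coli replicate 2 (-0.18, adjusted p = 0.319) or 3 (-0.21, adjusted p = 0.141), and lay at -0.79 without replicate 1. Nor was it called after quantile (-0.33, adjusted p = 0.0733) or cyclic loess normalization (-0.27, adjusted p = 0.0891), with arrays of the same title number averaged (-0.19, adjusted p = 0.0897) or with only the groups compared in the fit (-0.38, adjusted p = 0.0617). The glue list lay at 1.77 without wild type E. coli replicate 2 and the muscle list at -0.24 without dorsal mutant replicate 3, both still called. Male germline genes had a median of 0.60 (adjusted p = 0.0343, but adjusted p = 0.759 with an estimated correlation) with no member called, Mst84Db at 1.57 and ocn at 1.19, and none when adjusted over the list alone. That list was not called without dorsal mutant replicate 2 (0.62) or 3 (0.48, adjusted p = 0.148) or without wild type E. coli replicate 2 (0.32, adjusted p = 0.319) or 3 (0.53, adjusted p = 0.177), and lay at 1.04 without replicate 1. It was not called either with no filter (0.39, adjusted p = 0.0865), under the stricter filter (0.68, adjusted p = 0.0753), with only the groups compared in the fit (0.60, adjusted p = 0.0617) or with arrays of the same title number averaged (0.52, adjusted p = 0.133). The other 19 lists did not pass, with medians from -0.28 to 0.56. With the glue level as a covariate, chosen after seeing the data, the respiratory chain and muscle medians were -0.31 and -0.19, still called, and those of the glue, cuticle and male germline lists were -0.58, 0.16 and 0.095, none of them called. The covariate is made from the glue signals themselves, so the loss for the glue list follows from the fit.

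Besides Sgs4, other single genes differed in the dorsal mutant. Pepck1, the phosphoenolpyruvate carboxykinase gene, read 314.6, 66.5 and 4921.4 signal units against 10603 ± 2934 in wild type with E. coli, or -3.98 (SE 0.78). The calcium-binding protein gene Scp2 fell by 4.51 (SE 0.65), and Cpr67Fa2, a cuticle gene (-5.11, SE 0.41), Cyp12d1-d (-4.09), CG17290 (-3.53), CG42562 (-3.43) and the glutathione S-transferase gene GstD7 (-3.17) fell too. The P450 gene Cyp4e3 rose by 3.34 (SE 0.47), from 1648.9 ± 167.9 to 20193 ± 11188 units. CG11854, the cuticle gene Cpr78E, CG7606, CG16727, CG17191, CG9021, CG1304 and alpha-Est2 rose by 3.41 to 4.75. The unnamed 141407_at and 150902_at rose by 7.22 and 1.86, and 147431_at (-3.69) and 143097_f_at (-3.59) fell. There were 187 probe sets called higher and 215 lower, and 1818 had an unadjusted p under 0.05. With arrays of the same title number averaged, which joins dorsal mutant replicates 1 and 2, the total was 71. It was 674 with array weights, 194 without the variance trend and 234 with only the groups compared in the fit. The count was 221 and 236 without dorsal mutant replicates 1 and 2, 172 and 145 without wild type E. coli replicates 2 and 3, and 103 with the glue level as a covariate. Of 49 called genes that the naming rule took, 26 kept their calls without each array, and those that did not were CG11854, Cpr78E, CG7606, CG9021, Def, PGRP-SC2, SPE, casp, PPO1, Pxn, NimC2, Tep4, br, Edg91, LysX, Ser6, Zasp52, up, GstD5, GstZ1, ATPsynO, ND-51 and ND-75, at adjusted p between 0.0511 and 0.228.

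**Figure D2:**
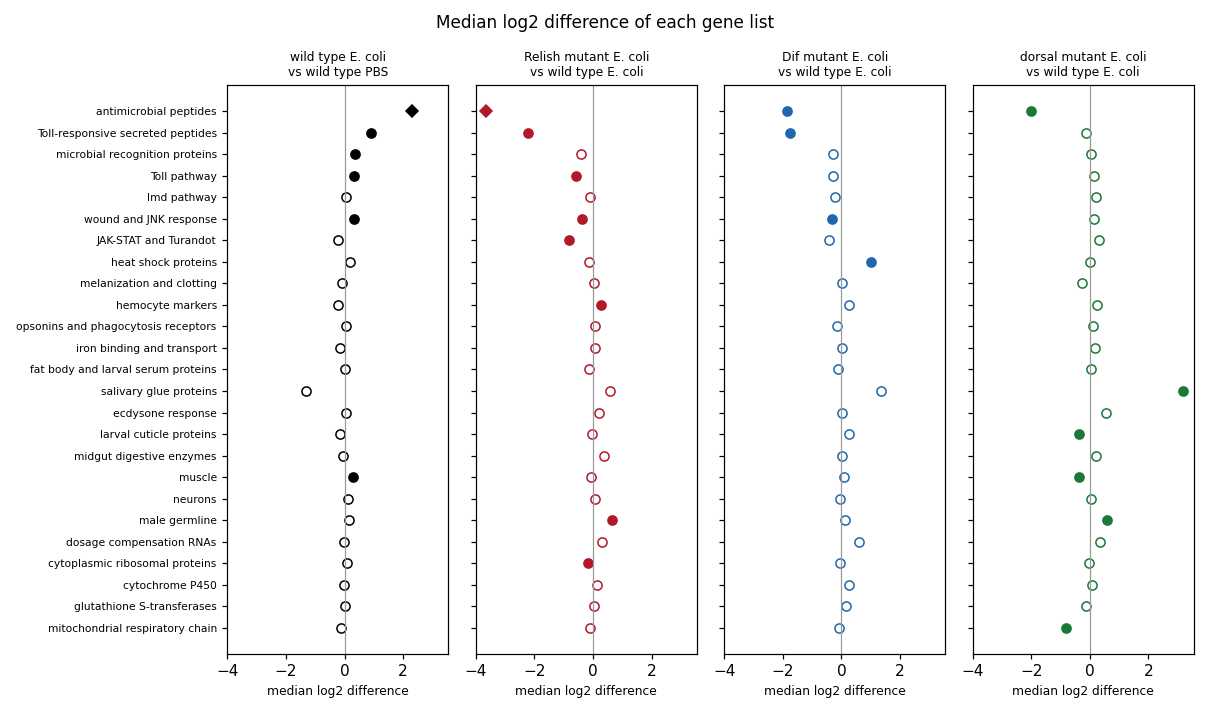
Each row is a gene list and each panel a comparison, with the median log2 difference of the list on the horizontal axis; filled points passed at the preset correlation, diamonds passed with an estimated correlation too, and open points did not pass. The antimicrobial peptide list lies at 2.32 in wild type with bacteria against PBS and at -3.66, -1.86 and -2.01 in the Relish, Dif and dorsal mutants against wild type with bacteria.

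Set against wild type larvae with PBS, the median of these peptides stood close to the level without bacteria in the mutants, while single genes varied. The antimicrobial peptide list had a median log2 difference of 0.50 in the Dif mutant (camera adjusted p = 0.406) and 0.29 in the dorsal mutant (adjusted p = 0.584). In the Relish mutant it lay at -0.61 (adjusted p = 0.0174, but adjusted p = 0.709 with an estimated correlation). That call was lost without wild type PBS replicate 3 (-0.59, adjusted p = 0.0575), without Relish mutant replicate 2 (-0.42, adjusted p = 0.147) and under the stricter filter (-0.61, adjusted p = 0.0658). No single member was called in any of the 3, and 2 were lower in the Relish mutant when adjusted over the list alone. The 95% interval of DptB was from 0.03 to 1.94 in the Dif mutant, from -0.10 to 1.81 in the dorsal mutant and from -1.80 to 0.11 in the Relish mutant. Of the 17 probe sets raised by bacteria in wild type, 0, 0 and 1 were called above wild type PBS in the Relish, Dif and dorsal mutants, and 2, 4 and 5 had an unadjusted p under 0.05. The medians of the 17 were -0.52, 0.47 and 0.71 against wild type PBS, where bacteria in wild type gave 3.31. The 17 were picked by that same comparison in wild type, so 3.31 is likely too high. The medians against the same PBS arrays may be too high as well. Among the 17 the unnamed 143443_at stood at -0.52, 2.01 and 1.74, so part of a response is not excluded in the Dif and dorsal mutants.

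The mutants were also compared with each other, which takes the shared wild type arrays out. The antimicrobial peptide list was lower in the Relish mutant than in the Dif mutant (median -0.95, camera adjusted p = 2.43e-04, but adjusted p = 0.170 with an estimated correlation) and than in the dorsal mutant (-0.85, adjusted p = 0.00267, but adjusted p = 0.278 with an estimated correlation). The member called in both was Mtk, at -3.08 (SE 0.58) and -2.75 (SE 0.58); it lost the call without Relish mutant replicate 1 in both, without Dif mutant replicate 2 in the former and without dorsal mutant replicate 1 in the latter, at adjusted p between 0.0510 and 0.0812. Rel was lower by -3.67 (SE 0.34) and -3.23 (SE 0.34). Between the Dif and dorsal mutants the list did not differ (median 0.17, adjusted p = 0.718), and its members lay between -0.04 and 0.34, with SEs of 0.41 to 0.58. Toll-responsive secreted peptides were lower in the Relish than in the dorsal mutant (-1.93, adjusted p = 6.29e-05, but adjusted p = 0.278 with an estimated correlation) and lower in the Dif than in the dorsal mutant (-1.69, adjusted p = 6.22e-05, but adjusted p = 0.257 with an estimated correlation). Respiratory chain genes were higher in the Relish (0.64, adjusted p = 4.58e-09, but adjusted p = 0.373 with an estimated correlation) and Dif mutants (0.58, adjusted p = 5.95e-07, but adjusted p = 0.416 with an estimated correlation) than in the dorsal mutant. These stayed called at 0.37 and 0.24 without dorsal mutant replicate 3 and at 0.37 and 0.34 with the glue level as a covariate, and the latter at 0.36 with array weights.

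Further lists differed between the mutants. Heat shock proteins were higher in the Dif mutant: they lay at -1.16 for Relish against Dif (adjusted p = 3.95e-08, but adjusted p = 0.0806 with an estimated correlation), with 2 of 9 members called lower, and at 0.95 for Dif against dorsal (adjusted p = 4.23e-05, but adjusted p = 0.257 with an estimated correlation), with 2 called higher. The JAK-STAT list of 3 genes lay at -1.26 for Relish against dorsal (adjusted p = 4.84e-04, but adjusted p = 0.0875 with an estimated correlation), with 2 members called lower, and at -0.93 for Dif against dorsal (adjusted p = 0.0187, but adjusted p = 0.257 with an estimated correlation), with 1 called lower. With no filter, listed genes of lower signal joined these 3, and the median was 0.0644 and 0.0482, not called in either. The differences of the 3 genes themselves do not depend on the filter. With the glue level as a covariate the JAK-STAT list was not called for Dif against dorsal (-0.77, adjusted p = 0.0636). For Relish against dorsal the Toll pathway (-0.51), Imd pathway (-0.30), glue (-2.49) and cuticle lists (0.31) passed at adjusted p = 0.0283, 0.0329, 0.0266 and 0.0283, but with an estimated correlation the adjusted p was 0.373, 0.373, 0.460 and 0.373. None of the 4 was called without dorsal mutant replicate 3 (-0.26, -0.23, -2.02 and 0.39), the first 2 not without Relish mutant replicate 1 (-0.13 and -0.24) and the last 2 not without replicate 2 (-0.48 and 0.21). With the glue level as a covariate the Toll pathway (-0.34, adjusted p = 0.0626), Imd pathway (-0.13, adjusted p = 0.100) and cuticle lists (0.21, adjusted p = 0.311) were not called, nor was the glue list, from whose own signals the covariate is made. The stricter filter ended the calls of the Toll pathway (-0.17, adjusted p = 0.117) and glue lists (-2.49, adjusted p = 0.0651), and array weights those of the Imd pathway (-0.28, adjusted p = 0.0579) and cuticle lists (0.32, adjusted p = 0.0579). For Dif against dorsal the ecdysone (-0.55), cuticle (0.58), muscle (0.30), male germline (-0.54) and glutathione S-transferase lists (0.44) passed at adjusted p = 0.0444, 0.0187, 0.0246, 0.0322 and 0.0246, but with an estimated correlation the adjusted p was 0.402, 0.402, 0.402, 0.541 and 0.402. Of these the muscle list lost its call without Dif mutant replicate 1 (0.18) or dorsal mutant replicate 2 (0.23), and the other 4 lost theirs without dorsal mutant replicate 3 (-0.34, 0.35, -0.43 and 0.55). The ecdysone list did so without Dif mutant replicate 3 too (-0.41), and the male germline list without Dif mutant replicate 2 (-0.41) or dorsal mutant replicate 2 (-0.51). With the glue level as a covariate none of the 5 was called (-0.54, 0.38, 0.24, -0.21 and 0.31, at adjusted p = 0.0903, 0.0903, 0.0809, 0.189 and 0.0903). Array weights ended the calls of the ecdysone (-0.45, adjusted p = 0.0970), male germline (-0.46, adjusted p = 0.0814) and glutathione S-transferase lists (0.60, adjusted p = 0.0922). The stricter filter ended those of the ecdysone (-1.23, adjusted p = 0.0552), muscle (0.21, adjusted p = 0.0552) and male germline lists (-0.57, adjusted p = 0.187), and no filter those of the ecdysone (-0.18, adjusted p = 0.184) and muscle lists (0.25, adjusted p = 0.0541). The muscle list was not called after cyclic loess normalization (0.26, adjusted p = 0.0665), nor the ecdysone list with the pseudocount doubled (-0.45, adjusted p = 0.0513). For Relish against Dif the male germline list lay at 0.52 (adjusted p = 0.0266, but adjusted p = 0.816 with an estimated correlation) and was not called without Relish mutant replicate 1 (0.42) or Dif mutant replicate 2 (0.35) or 3 (0.50), or under the stricter filter (0.49, adjusted p = 0.151). With calls kept, the Toll pathway list lay at -0.20 without dorsal mutant replicate 1 and at -0.29 and -0.28 without Relish mutant replicates 2 and 3, and the muscle list at 0.49 without Dif mutant replicate 3 and 0.47 without dorsal mutant replicate 3.

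Relish mutant arrays read 77.0 ± 32.0 signal units of Alp7, against 18147 ± 7584.7 in the Dif mutant and 8118.7 ± 2757.3 in the dorsal mutant. Against the Dif mutant, CG17105, CG3819 and Jig were higher by 7.06 (SE 0.51), 4.22 (SE 0.80) and 3.78 (SE 0.66), and Alp7, Hsp26 and CG1304 differed by -6.79, -5.85 and -4.13. Against the dorsal mutant, Pepck1, Scp2 and CG11334 were higher in the Relish mutant by 4.61, 4.18 and 2.91, and Alp7, the antibacterial peptide gene Listericin and the serine protease gene Jon66Cii differed by -5.68, -3.96 and -3.85. Pepck1, Hsp26 and Scp2 were higher in the Dif than in the dorsal mutant by 4.61, 4.42 and 3.72, and CG17105, Cyp4e3 and CG11854 differed by -7.24, -5.21 and -4.91. The called probe sets numbered 75 higher and 56 lower in Relish against Dif, 179 and 169 in Relish against dorsal, and 267 and 325 in Dif against dorsal. With arrays of the same title number averaged the totals were 96, 87 and 152, without the variance trend 67, 167 and 378, and with only the groups compared in the fit 87, 71 and 161. With the glue level as a covariate the total for Relish against dorsal was 139. CG3819 lost its call against the Dif mutant without Dif mutant replicate 2 or 3 or Relish mutant replicate 2, and CG11854 without Dif mutant replicate 2 or 3. The total for Relish against Dif was 72 without Dif mutant replicate 2 and 61 and 67 without Relish mutant replicates 1 and 2. That for Relish against dorsal was 177 and 172 without dorsal mutant replicates 1 and 2 and 143 and 114 without Relish mutant replicates 1 and 2. That for Dif against dorsal was 228 and 352 without Dif mutant replicates 2 and 3 and 272 and 323 without dorsal mutant replicates 1 and 2.

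**Figure D3:**
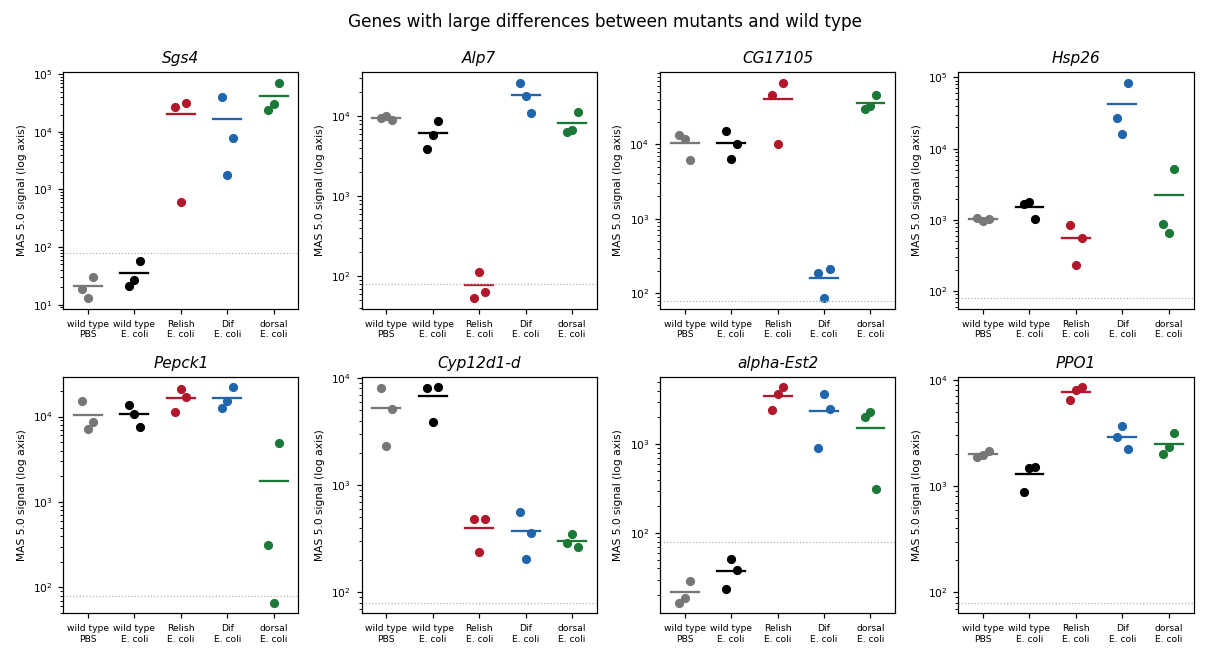
Each panel plots the signal of 1 gene on a log axis for the 15 arrays by group, with points for arrays, bars for group means and a dotted line at the pseudocount of 80. Sgs4 and alpha-Est2 read below the pseudocount on all 6 wild type arrays and above it on all 9 mutant arrays, and Alp7 was at 77.0 ± 32.0 units in the Relish mutant.

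Calls against wild type with bacteria overlapped between the mutants. Relish and Dif shared 28 probe sets called higher and 58 called lower, Relish and dorsal 36 and 46, and Dif and dorsal 37 and 49. Independent lists of these sizes would share 0.967 and 2.00, 1.39 and 2.45, and 2.13 and 3.31. All 3 mutants shared 20 higher and 30 lower, where independent lists would share 0.0158 and 0.0377. Among the 30 were Rel, DptB, CecB, Def, PGRP-SB1, ple, SPE and CG14567, and among the 20 were Sgs4, alpha-Est2, CG17191, CG16727, PPO1 and the unnamed 141407_at. In 100 simulated sets of unchanged mutants against the shared wild type arrays no call was shared. With nothing changed almost no probe set can pass the adjustment. That 0 therefore cannot show how many of the shared calls come from sharing these arrays. The covariance of log2 differences over probe sets was 0.212, 0.193 and 0.163 for the 3 pairs, against 0.0833, 0.0830 and 0.0830 simulated. The simulated part comes from sharing these arrays, and less that part the covariance was 0.129, 0.110 and 0.0798. The correlations were 0.563, 0.500 and 0.415, against 0.500, 0.498 and 0.499 simulated. By that measure Relish and Dif lay above the simulated value, Relish and dorsal level with it, and Dif and dorsal below it. The wild type E. coli arrays are too few to be split, so part of the excess of shared calls over independent lists may come from sharing them. Without wild type E. coli replicate 3 the count shared by all 3 mutants was 26, and with arrays of the same title number averaged it was 21.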

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

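The tests in this part were chosen after the result had been seen, except the comparisons between mutants, the tests with the glue level as a covariate, the removal of dorsal mutant replicate 3, the respiratory chain genes under quantile normalization and the splits of the arrays; the covariate itself was added after seeing the data.

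Direct tests between mutants found 131 called probe sets for Relish against Dif, 348 for Relish against dorsal and 592 for Dif against dorsal, so the 3 mutants, set against the same wild type, differed from each other. The antimicrobial peptide list lay at -0.95 for Relish against Dif (adjusted p = 2.43e-04, but adjusted p = 0.170 with an estimated correlation) and at -0.85 for Relish against dorsal (adjusted p = 0.00267, but adjusted p = 0.278 with an estimated correlation). For Relish against Dif the named differences were CG17105 at 7.06, CG3819 at 4.22, Jig at 3.78, Alp7 at -6.79, Hsp26 at -5.85 and CG1304 at -4.13. For Relish against dorsal they were Pepck1 at 4.61, Scp2 at 4.18, CG11334 at 2.91, Alp7 at -5.68, Listericin at -3.96 and Jon66Cii at -3.85. For Dif against dorsal they were Pepck1 at 4.61, Hsp26 at 4.42, Scp2 at 3.72, CG17105 at -7.24, Cyp4e3 at -5.21 and CG11854 at -4.91.

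As a group, the genes that bacteria raised in wild type were near the PBS level on the Dif and dorsal mutant arrays. The authors' scaling is argued against as the cause, since after quantile normalization the antimicrobial peptide list still lay at -1.89 in the Dif and -2.04 in the dorsal mutant against wild type with bacteria. A difference in larval stage, as far as the glue level measures it, is argued against for the dorsal mutant. There the shift was -2.18 with the glue level as a covariate, though that level did not overlap between the dorsal mutant and wild type E. coli arrays. It stays open whether these larvae lacked bacteria, as the letters in their titles could mean, or whether the mutation lowered the response. The list lay at 0.50 in the Dif and 0.29 in the dorsal mutant against wild type PBS, neither called. These causes cannot be told apart because no PBS-injected mutants were analysed here. The same question stays open for the Relish mutant arrays, whose titles hold the same letters. Their list lay at -0.61 against wild type PBS. RNA integrity stays open too: the 3' to 5' ratio of actin was 1.99, 1.65 and 1.71 on the Dif, 4.09, 4.95 and 1.83 on the dorsal and 2.36, 5.28 and 3.41 on the wild type E. coli arrays.

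The 3 mutants shared 50 probe sets called in the same direction. For the 20 that were higher, chance values of the shared wild type E. coli arrays are argued against. Of these, 16 were also called higher in all 3 mutants against wild type PBS. For those 16 a missing bacterial response is argued against too, since it would leave the mutants at the level of wild type PBS. Of the 20, 3 had an unadjusted p under 0.05 for a fall with bacteria in wild type, a count that cannot decide because small changes are seldom found. A missing response stays open for the probe sets not among the 16. One of them, CG7149, read -1.23 for bacteria in wild type and 0.07, 0.05 and -0.02 in the Relish, Dif and dorsal mutants against wild type PBS. For the 30 that were lower, chance values of the wild type E. coli arrays are argued against for those picked again with 1 such array left out. With replicate 1, 2 or 3 left out, 18, 22 and 11 probe sets were picked, of which 15, 20 and 11 are among the 30. They lay above the mutants on the array left out by medians of 3.50, 3.21 and 3.80, against 3.35, 3.45 and 3.76 on the arrays used. Replicates 2 and 3 share a title number and may come from 1 culture or extract. Only the set without replicate 1 was thus read on an array of another title number than those used. Of the 30, which had a median of 1.92 for bacteria in wild type, 12 were called higher there, 27 lay closer to wild type PBS than to wild type E. coli and 6 were also called lower than wild type PBS in all 3 mutants, but a lower baseline with an intact response could give these values too, so a missing response and a stock background cannot be told apart for them. In total 22 of the 50, 16 of the higher and 6 of the lower ones, also differed the same way from wild type PBS in all 3 mutants, and a stock background common to the mutants cannot be told apart from the mutations, because every mutant array comes from another stock than wild type and no PBS-injected mutants were analysed here.

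The respiratory chain list lay at -0.80 in the dorsal mutant against wild type with bacteria. The authors' scaling is argued against, with -0.73 after quantile normalization. The single array that correlated least with its group is argued against as the whole cause, with -0.56 without dorsal mutant replicate 3. Against the dorsal mutant, however, the list went from 0.64 to 0.37 in the Relish and from 0.58 to 0.24 in the Dif mutant without that array. The dorsal mutant arrays left then share a title number and may come from 1 culture or extract. The shift against wild type was -0.31 with the glue level as a covariate. A difference in larval stage between the pools is therefore a candidate explanation for most of that shift. The glue level did not overlap between the dorsal mutant (14.72 to 15.47) and wild type E. coli arrays (9.21 to 13.47). It includes Sgs4, which was low on all wild type arrays, so the covariate can take out an effect of the stock as well. The glue level was highest on the dorsal mutant arrays, so an effect of the mutation on either stage or respiratory chain genes stays open and untested.

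For each of the 7 comparisons the 6 arrays can be split in 10 ways, too few for a share under 0.05, and the real split was the 1 with the most calls in each. Bacteria in wild type gave 18 calls against at most 4 in another split. The Relish mutant gave 215 against 1, the Dif mutant 306 against 0 and the dorsal mutant 402 against 0. Relish against Dif gave 131 against 2, Relish against dorsal 348 against 1, and Dif against dorsal 592 against 2.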

How the results depend on the processing

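The block of the wild type arrays alone and the glue covariate were chosen after seeing the data. The signal over background was not separated by detection calls, so values near the pseudocount are limits of this array rather than levels. The antimicrobial peptide shifts in wild type (1.90 to 2.60 with an array left out) and in the Relish mutant (-3.90 to -3.50) kept their direction and call under all alternatives run. Those of the Dif mutant (-2.14 to -1.58) and the dorsal mutant (-2.33 to -1.62) did so except with an estimated correlation (-1.86, adjusted p = 0.0898, and -2.01, adjusted p = 0.0592), the adjusted p being at most 1.48e-04 and 5.50e-05 under the others. Against wild type PBS the Relish mutant's shift of -0.61 was no longer called under the stricter filter (-0.61, adjusted p = 0.0658) or with an estimated correlation (-0.61, adjusted p = 0.709; from 0.00668 to 0.147 under the others), and ran from -0.82 to -0.42 with an array left out; the Dif and dorsal mutants' shifts ran from 0.46 to 0.67 and from 0.22 to 0.60, and the dorsal one was -0.0118 with the glue covariate. Calls for bacteria in wild type numbered 58 with array weights, 31 with only the 6 arrays fitted and 10 to 18 with an array left out. With arrays of 1 title number averaged, which leaves fewer samples, calls were 94 for Relish, 110 for Dif and 71 for dorsal against wild type, 87 for Relish against dorsal, 152 for Dif against dorsal and 21 shared by all 3 mutants. Without the variance trend they were 184 for Dif, 194 for dorsal, 67 for Relish against Dif, 167 for Relish against dorsal and 378 for Dif against dorsal. With only the groups compared in the fit they were 164 for Dif, 234 for dorsal, 87 for Relish against Dif, 71 for Relish against dorsal and 161 for Dif against dorsal. Array weights gave 674 for dorsal. The glue covariate gave 103 for dorsal and 139 for Relish against dorsal. With an array left out the counts ran from 116 to 167 for Relish, 153 to 224 for Dif, 145 to 376 for dorsal, 61 to 119, 114 to 306 and 228 to 604 for the pairs, and 26 to 51 for those shared by all 3. For these counts under the settings that keep all arrays the cause was not tested. With no filter the JAK-STAT median went from -1.26 to 0.0644 for Relish against dorsal and from -0.93 to 0.0482 for Dif against dorsal. There listed genes of lower signal joined the list, while the differences of its main members do not depend on the filter. With the glue covariate the glue list turned from 3.20 to -0.58 for dorsal and from -2.49 to 0.0190 for Relish against dorsal. That follows from a covariate made of the same signals. The cuticle list turned from -0.38 to 0.16 for dorsal with the covariate. Whether replicate numbers pair the wild type arrays stays open. Deviations of the wild type E. coli and PBS arrays of the same number correlated at 0.340, 0.180 and 0.0763. Other numbers reached -0.083 for number 1, 0.0145 for number 2 and 0.0932 for number 3, so numbers 1 and 2 were closest to their own. In each of the other comparisons at least 1 number was closer to another number. With the replicate number as a block the 7 counts were 21, 234, 326, 468, 158, 405 and 676, within 1.5 times of the main ones. A block in the 6 wild type arrays alone gave 87, against 31 for these arrays without the block. Of 165 called results for named genes, 127 kept their call under all of 7 settings (both normalizations, both pseudocounts, no filter, no trend, weights), and none changed sign under any setting. Calls were lost by 68 of the 165 with arrays of 1 title number averaged, by 39 with only the groups compared in the fit and by 38 with the glue covariate.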

Other observations

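The glue gene Sgs3, the Hsp70 probe set and the ribosomal RNA control were chosen after their values were seen. Digestive and detoxification genes differed between mutants and wild type in some members, while their lists did not pass in any mutant against wild type with bacteria. The list test looks for a shift in 1 direction, so a list whose members go both ways need not pass. Among the midgut enzymes the serine protease gene Jon66Cii was lower in the Relish (-3.46) and Dif mutants (-1.86), and the lysozyme gene LysX was lower in the Relish (-1.94), Dif (-1.68) and dorsal mutants (-1.29). Of 72 cytochrome P450 genes, 4 rose and 1 fell in the Relish mutant, 3 rose and 6 fell in the Dif mutant, and 7 rose and 5 fell in the dorsal mutant. Of all 11427 probe sets, 215, 306 and 402 were called in these 3 comparisons. Cyp6a14 was lower in the Dif (-3.95) and dorsal mutants (-2.90), and Cyp6a23 in the dorsal mutant (-2.60). Of 31 glutathione S-transferase genes, GstE8 was called lower in the Relish and dorsal mutants (-2.45 in the latter), and GstE5 rose by 1.65 in the Relish mutant and 1.62 in the Dif mutant. The iron transport gene Tsf3 was lower in all 3 mutants, at -1.98, -2.73 and -2.40, and read 1.93 for bacteria in wild type, where it was not called (adjusted p = 0.134). The calls of Jon66Cii in the Dif mutant, LysX in the Dif and dorsal mutants, and GstE8 and Tsf3 in the Relish mutant were lost without 1 or more of the arrays.

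Blood cell genes rose in single members as well. In the dorsal mutant Hml, a hemocyte gene, rose by 1.27 and the peroxidase gene Pxn by 1.02, and NimC1 rose by 1.98 in the Dif mutant; of these, Hml kept its call without each of the arrays. PPO1 was called higher in all 3 mutants, at 2.52, 1.15 and 0.93, but the calls in the Dif and dorsal mutants were lost without several of the arrays.

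Sgs4 read between 13.0 and 57.9 signal units on the 6 wild type arrays and between 615.2 and 70675 on the 9 mutant arrays. Another glue gene of the list, Sgs3, read up to 41937 in wild type with E. coli and down to 17.3 on Relish mutant replicate 2.

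A probe set shared by several Hsp70 genes read 40682 and 8464.1 signal units on Dif mutant replicates 2 and 3, 281.2 on replicate 1, and at most 712.9 on the other arrays. The control probe set for the middle of 18S ribosomal RNA read 8487.7 on Relish mutant replicate 2 and 594.0 on replicate 3, and between 768.5 and 4471.6 on the arrays of the other groups.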
